A study of Rattus norvegicus with 14 samples.

How the data were processed

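Gene expression was measured in rat left ventricle (heart) and in soleus, a slow muscle of the hind leg, with arrays carrying 1185 probes. Per the labels, total RNA was extracted with Tri-Reagent and the RNA-derived target was labelled with radioactive phosphorus in dATP by a Clontech protocol. Each tissue was sampled under 7 conditions, which gave 14 samples with 1 sample per tissue and condition. Per the labels' protocols, 3 pools were made for each group, and 6 animals are mentioned without saying whether this is per pool or in all. The files hold 1 value per probe and sample, and whether that value is a mean of the pools is not given in the sources used here.

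The deposited per-sample values are intensities on a linear scale, in arbitrary units. For 4 of the samples the deposited values are of the same kind, but some lines hold a probe with no second cell, so that their unit was recorded as other, a format remark and not a different scale. Image software, background subtraction and scaling between arrays are not given in the sources used here. In the 12 treated samples no deposited value lies under 1200, and 39.3% of the cells are empty. The 2 untreated samples hold a value for every probe, reaching down to 69.03 in heart and 126.2 in soleus. The deposited series table holds a second intensity for each probe and sample, in relative units, with a column median of 0.253 in the heart control, 0.371 in the soleus control and 0.722 to 1.25 in the treated samples. Its empty cells are the same ones as in the per-sample values, its direction is the same, and what it is relative to stays unknown. It was used as an alternative.

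The probe identifiers are 702 with the prefix R and 483 with the prefix RG. The sources used here do not pair them with genes, and 0 of them were found in the reference gene table. Therefore 23 gene lists fixed before the data were examined were not tested, no gene is named, and at most 2 probes in each direction are given for a comparison. The rule, fixed before the data were examined, took the probes with the lowest adjusted p in each direction among those past 0.05. Where fewer than 5 passed in a direction, the probes with the largest moderated statistic were taken and are given as values.

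The plan had assumed a value for every probe. Because the treated samples are empty under 1200, the same limit was applied to the untreated samples, and a probe is called measured in a sample where its intensity is at least 1200. Values under the limit or empty were entered at 1200. The 14 samples were quantile-normalized with limma 3.58.1 in R 4.3.3. The lowest measured value differs between samples after this step, so the highest of these minima, 2040, served as a common floor for the fits, and lower values were raised to it. Values were then transformed as log2(intensity + 1219), where 1219 is the 10th percentile of the positive deposited intensities. A fold change on this scale understates the change of probes with low intensity, more so where a value lies at the floor. A probe entered the fits when it lay above the common floor in at least 7 of the 14 samples, which 531 probes did (44.8%). Of the 1185 probes, 261 were measured in all samples, 222 lay above the common floor in all samples and 53 were measured in none.

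For each treated sample and the untreated sample of its tissue, probes measured in both, with an intensity at or above its sample's median in at least 1 of them, were compared. Those whose normalized intensity plus 1219 differed at least 2-fold were counted. A 2-fold count on this scale therefore asks for more than a 2-fold ratio of the normalized intensities themselves. The common floor was not applied there. With 1 sample per group these counts have no test. For tests across samples, limma linear models with empirical Bayes moderation were fitted to all 14 samples, so that the factors of the design replicate one another. An additive model held tissue, heat, exercise and duration (long, short or untreated) and had 9 residual degrees of freedom. A model with tissue by treatment products had 6, a model with a heat by exercise product had 8, and the comparison of soleus with heart within the 7 conditions had 6. Interactions left out of a model enter its residual. Tests were two-sided, with Benjamini-Hochberg adjustment over the 531 probes at 0.05. The labels do not say that the samples come from separate animals, so the p-values measure the spread between these samples, and their number limits the precision.

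The fits were tested on simulated data of 1185 probes with 200 changed probes per run in 5 runs and a noise SD of 0.309 on the log2 scale. For exercise, 56.2% of probes changed 1.5-fold and 91.6% of those changed 2-fold were recovered among a mean of 646 tested. For heat these shares were 61.8% and 95.6% among a mean of 653, and for tissue 56.5% and 94.3% among a mean of 669. All recovered probes had the right sign. Of the probes called, 10.3% were false for heat, 6.94% for exercise and 8.78% for tissue, above the nominal 5%.

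Alternatives comprised scaling by the median, no normalization, the relative intensities of the series table, other pseudocounts, looser and stricter filters, other model terms, subsets of the conditions and leaving out each sample in turn. An analysis without a pseudocount, one without the control and long heat samples, one with tissue and exercise as the only terms and one with the condition as a random block (limma's duplicateCorrelation) were added after seeing the data. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.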

Results

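Expression was measured in heart (left ventricle) and soleus muscle of rats kept under 7 conditions. These were no treatment, heat acclimation at 34°C for 2 days or 1 month, treadmill exercise training at 24°C for 3 days or 1 month, and heat acclimation combined with exercise for 3 days or 1 month. Heat acclimation is prolonged exposure to moderate environmental heat. Each combination of tissue and condition was represented by 1 sample, so a single sample has no replicate error. The number of probes measured, that is at an intensity of 1200 or more, ranged from 594 in the control to 752 after long exercise in heart. In soleus it ranged from 531 after short heat to 945 after long exercise, with 728 in the control. Over the 261 probes measured in all samples, the median intensity lay between 5564 and 7059 in heart. In soleus it lay between 3879 after short heat and 7592 after long combined treatment.

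The first question was how each treatment differed from no treatment within a tissue. Differences of at least 2-fold are counted here on normalized intensity plus the pseudocount of 1219. In soleus, 146 such differences were counted in 2501 comparisons of a probe over the 6 treatments, 105 higher and 41 lower than in the control. In heart, 47 were counted in 2147 comparisons, 31 higher and 16 lower. All 6 counts of a tissue share its 1 control. The soleus control was unusually like the heart control, as given below. The higher count in soleus therefore cannot be told apart from an unusual control. Short heat gave the highest count in both tissues, except in soleus when both samples had to lie at or above the median, where it gave 4, short combined treatment 6 and long exercise 7. In heart, 16 probes were higher and 6 lower of 307 compared (7.17%), and in soleus 35 were higher and 9 lower of 367 (12%). The soleus short heat sample was also the one with the lowest median intensity and the fewest probes measured. In heart, the short heat sample had the lowest median intensity, 5564, and the fewest probes of the treated samples, 612. Its median rank correlation with the other heart samples, 0.826, was the lowest in that tissue, as was that of the soleus short heat sample in soleus, 0.797. A weaker array cannot be told apart from a response to heat in these counts. Long heat gave 3 higher and 0 lower of 355 probes in heart, and 4 higher and 0 lower of 410 in soleus. The long heat samples, like the controls, were unusually alike between the tissues, so these low counts need not mean a small response.

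In heart, short exercise gave 3 higher and 5 lower probes of 368, long exercise 2 and 4 of 382. Short combined treatment gave 2 and 0 of 366 probes in heart, and long combined treatment 5 and 1 of 369. In soleus, short exercise gave 12 higher and 8 lower probes of 424, and long exercise 19 and 9 of 475. The combined treatments in soleus gave 19 and 6 of 382 probes when short, and 16 and 9 of 443 when long. The SD of the log2 ratio over the compared probes ran from 0.322 (long heat) to 0.53 (short heat) in heart, and from 0.352 (long heat) to 0.643 (short heat) in soleus. These counts compare single samples and carry no test. They depend on the pseudocount and the scaling, and without the pseudocount they came to 125 in heart and 345 in soleus. The split moved with the scaling, from 66% higher in heart to 81.7% under median scaling and 82.6% without normalization. In soleus it went from 71.9% higher to 91.2% under median scaling and 44.4% without normalization. Without normalization the direction turned in soleus after short heat, to 7 higher and 76 lower probes, and after short combined treatment, to 5 higher and 26 lower. In heart it turned after short exercise, to 9 higher and 5 lower under median scaling and 15 and 5 without normalization, and after long exercise, to 8 and 1 and to 9 and 1.

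**Figure D1:**
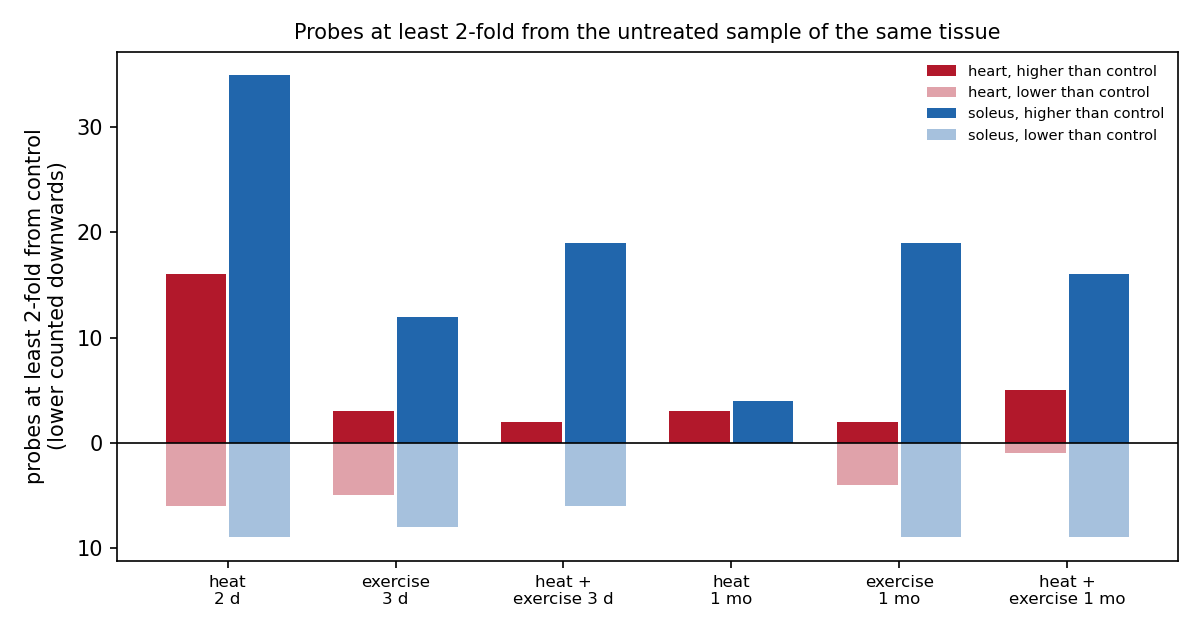
Number of probes at least 2-fold from the untreated sample of the same tissue (vertical axis, lower probes counted downwards from 0) for 6 treatments (horizontal axis), with heart in red and soleus in blue, dark for higher and pale for lower. The 2-fold limit holds for normalized intensity plus 1219. Bars are counts from single samples without error bars, and short heat has the highest bars, with 16 higher probes in heart and 35 in soleus.

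Exercise was compared with no exercise over both tissues and all heat conditions, that is 8 exercised against 6 unexercised samples. Of the 531 tested probes, 38 differed between exercised and unexercised samples, 29 higher and 9 lower with exercise (limma, Benjamini-Hochberg adjusted p at 0.05). The unexercised samples include the control and long heat samples, whose tissues were unusually alike, as given below. Without these samples the count came to 0. Probe R163 rose by 0.68 ± 0.10 (SE) on the log2 scale (limma adjusted p = 0.00329). Its normalized intensity was 4290 ± 861 (SD, n = 8) in exercised and 1570 ± 559 (SD, n = 6) in unexercised samples. R163 was measured in 8 of 8 exercised samples and in 2 of 6 unexercised ones, the others being entered at the limit. Probe RG099 rose by 0.65 ± 0.12 (limma adjusted p = 0.0127), from a normalized intensity of 2990 ± 1310 (n = 6) to 5290 ± 1170 (n = 8). Probe R252 fell, with a log2 effect of -0.73 ± 0.14 (limma adjusted p = 0.0127) and an intensity of 1920 ± 620 (n = 8) against 4730 ± 1510 (n = 6). Probe RG011 fell less, with an effect of -0.44 ± 0.10 (limma adjusted p = 0.0309) and an intensity of 11300 ± 2210 (n = 8) against 15200 ± 1800 (n = 6). Each of these 4 probes went the same way in 8 of 8 matched pairs of an exercised and an unexercised sample, pairs that partly share a sample.

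Of the 38 probes, 25 went the same way in all 8 matched pairs and 37 in at least 7. Their effects ranged in size from 0.327 to 0.77 on the log2 scale, and 38 of 38 had the same sign in heart and in soleus. The list was chosen for its mean effect over these same samples, which by itself favours such agreement between pairs and tissues. The number of probes measured was 765 ± 106 (SD, n = 8) in exercised and 638 ± 72 (SD, n = 6) in unexercised samples, a difference examined after seeing the data. Permuting within each tissue separately, which ignores that the tissues share conditions, gave p = 0.027 (exact permutation, two-sided, Benjamini-Hochberg adjusted p = 0.054 over heat and exercise). With the 7 conditions as units the exact permutation p was 0.14 (two-sided, 35 arrangements, adjusted p = 0.28). Under median scaling 33 probes rose and 11 fell, 34 of these 44 being among the 38. Without normalization 60 probes rose and 1 fell, 27 of these 61 being among the 38, and the median over the 222 probes above the floor in all samples shifted by 0.14 with exercise. In the long arms with the controls the count of 38 came to 61, with 30 higher and 31 lower, so the excess of higher probes was not kept there. It came to 0 with heart or soleus alone, 0 in the short arms with the controls and 1 without the controls. With a heat by exercise term, where the exercise effect is that in unheated samples alone, it came to 1. Without the control and long heat samples it came to 0. In that last set, with 5 residual degrees of freedom, the unexercised samples are those of short heat alone. All 38 kept their sign, 24 had an unadjusted p under 0.05 and the median size was 0.516 against 0.476. Of all 531 probes, 116 had an unadjusted p under 0.05 there. The list was chosen on samples that this set reuses, which by itself favours a kept sign and size.

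Leaving out a single soleus sample gave 1 call without the control, 7 without long heat, 9 without short exercise, 10 without short combined treatment, 11 without short heat, 12 without long combined treatment and 21 without long exercise. Leaving out a single heart sample gave 12 calls without the control, 16 without long heat, 21 without long exercise, 23 without long combined treatment, 31 without short combined treatment, 39 without short exercise and 84 without short heat. Those 84 were 50 higher and 34 lower. R163 kept an adjusted p under 0.05 in limma with any 1 sample left out, whereas RG099 and R252 lost it without the soleus control, with effects of 0.57 and -0.73. R163 lost it without both controls (limma adjusted p = 0.0746) and in the short arms with the controls (0.0679). It also lost it without the control and long heat samples and in each tissue alone. The same held with a heat by exercise term (0.0666), which gives the effect in unheated samples alone. The other 3 probes lost it in all these settings, with no change of sign. RG011 lost it without any 1 of 6 soleus samples, long exercise being the exception, with effects between -0.43 and -0.39.

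**Figure D2:**
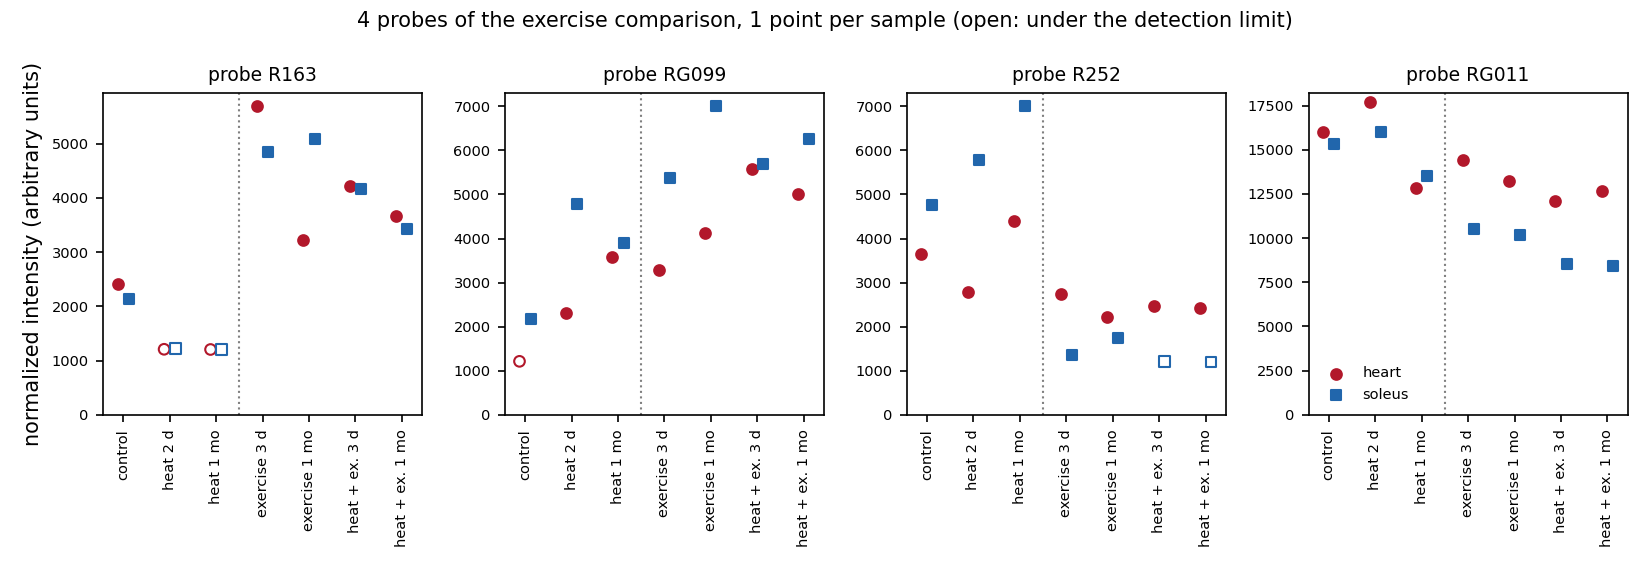
Normalized intensity in arbitrary units (vertical axis, linear from 0) of 4 probes in each of the 14 samples, with heart as red circles, soleus as blue squares and open symbols for values under the detection limit. Conditions are on the horizontal axis, with unexercised samples left of the dotted line, and each point is 1 sample without an error bar. R163 and RG099 have higher means in exercised samples (4290 and 5290) and R252 and RG011 lower ones (1920 and 11300).

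Heat was compared with no heat in the same model, 8 heated against 6 unheated samples. No probe passed the adjusted threshold (0 of 531 in limma), 39 had an unadjusted p under 0.05 where 26.6 would do so by chance, and the lowest adjusted p was 0.64. The probes nearest to it were R133, with a log2 effect of 0.27 ± 0.08 (SE), and RG246, with 0.31 ± 0.10, on the higher side. On the lower side these were R562, with -0.36 ± 0.11, and RG073, with -0.55 ± 0.19. RG073 was measured in 7 of 8 heated samples. It was empty in the heart short heat sample, without which its effect was -0.42. R562 was measured in 6 of 8 heated samples, and its effect ran from -0.66 with a heat by exercise term to -0.16 without the controls (limma adjusted p 0.0779 and 0.957). With that term the heat effect is the one in unexercised samples alone. R133 had a normalized intensity of 3200 ± 698 (SD, n = 8) in heated and 2400 ± 590 (n = 6) in unheated samples. The median standard error was 0.123 on the log2 scale for heat and for exercise alike. In simulated data 61.8% of 1.5-fold and 95.6% of 2-fold heat changes were recovered at this number of samples. Those runs each held 200 changed probes, with a noise SD of 0.309 and a mean of 653 tested probes. Adjusted p-values depend on how many probes change, so these shares do not carry over to a heat effect on fewer probes. They do not show that 2-fold heat changes would have been found here. Without normalization the median over the 222 probes above the floor in all samples shifted by -0.16 with heat. The number of probes measured was 683 ± 108 (n = 8) with heat and 748 ± 113 (n = 6) without (exact permutation within tissue, two-sided, p = 0.3, Benjamini-Hochberg adjusted p = 0.3, and p = 0.37 with the conditions as units).

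Long treatments were compared with short ones in the same model, 6 against 6 samples, with 2 days for short heat and 3 days for the other short treatments. In limma 0 of 531 probes passed, 53 had an unadjusted p under 0.05 and the lowest adjusted p was 0.239. RG278 had an effect of 0.53 and R251 one of -0.56 on the log2 scale. Without the soleus short heat sample 1 probe passed.

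Combined treatment was set against the sum of heat and exercise alone. In limma 0 of 531 probes departed from additivity, with 42 at an unadjusted p under 0.05 and a lowest adjusted p of 0.113. The standard error of this term had a median of 0.247. Tested without a filter on low values, 3 probes passed.

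Whether the tissues responded differently was tested as a difference of the effect between soleus and heart. For heat 0 of 531 probes passed in limma, 5 had an unadjusted p under 0.05 and the lowest adjusted p was 0.997. For exercise 0 passed, 50 had an unadjusted p under 0.05 and the lowest adjusted p was 0.202. Among the 38 probes called for exercise, 7 had an unadjusted p under 0.05 for the tissue difference and 0 passed when adjusted over the list alone, a list chosen on these samples. Within a single tissue 0 probes passed for exercise, with 55 at an unadjusted p under 0.05 in heart and 127 in soleus.

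Soleus was compared with heart within the 7 conditions. Of 531 probes, 29 were higher and 31 lower in soleus (limma, Benjamini-Hochberg adjusted p at 0.05), with sizes from 0.337 to 1.89 on the log2 scale. Probe RG148 was higher in soleus by 1.89 ± 0.18 (SE), at a normalized intensity of 21700 ± 6770 (SD, n = 7) against 4840 ± 1840 (SD, n = 7). Probe RG153 was higher by 1.24 ± 0.13, at 8190 ± 2050 against 2330 ± 1240 (n = 7 each), and was measured in 7 of 7 soleus and 5 of 7 heart samples. RG032 was lower in soleus, with an effect of -1.55 ± 0.15 and an intensity of 4160 ± 2010 against 13800 ± 1750 (n = 7 each). R638 was lower too, with -1.36 ± 0.13 and 2140 ± 1030 against 8120 ± 1410 (n = 7 each), and was measured in 6 of 7 soleus samples. R638 lay above the common floor in 9 and RG153 in 10 of the 14 samples, and their lower values were raised to it in the fit. These 4 probes had a limma adjusted p of 0.000104 and differed in the same direction in 7 of 7 conditions. Of the 60 probes, 49 did so in all 7 conditions and 59 in at least 6. The lists for tissue and exercise had 3 probes in common, where independent lists would have 4.29.

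The distance between the tissues differed by condition. Over the 222 probes above the common floor in all samples, the rank correlation between heart and soleus was 0.968 in the controls and 0.897 after long heat. It was 0.737 after short heat, 0.805 after short exercise, 0.809 after long exercise, 0.792 after short and 0.799 after long combined treatment. These correlations are across probes, which are not independent replicates. The heart and soleus controls were closer to each other than any pair of samples of the same tissue, whose highest correlation was 0.951. At least 2-fold differences between the tissues were found for 1 of the 222 probes in the controls and for 3 after long heat, against 20 after short heat, 7 after short exercise, 8 after long exercise, 14 after short and 9 after long combined treatment.

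Each sample was placed on an axis on which 0 is the mean of the exercised heart samples and 1 the mean of the exercised soleus samples, leaving a sample's own condition out of the means. The exercised heart samples lay between 0.011 and 0.148 and the exercised soleus samples between 0.802 and 1.03. The soleus control lay at 0.424 ± 0.046 (bootstrap SE over probes), the soleus long heat sample at 0.565 ± 0.063 and the soleus short heat sample at 0.766 ± 0.079. The heart control lay at 0.103 ± 0.049, the heart long heat sample at 0.051 ± 0.05 and the heart short heat sample at 0.302 ± 0.073.

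**Figure D3:**
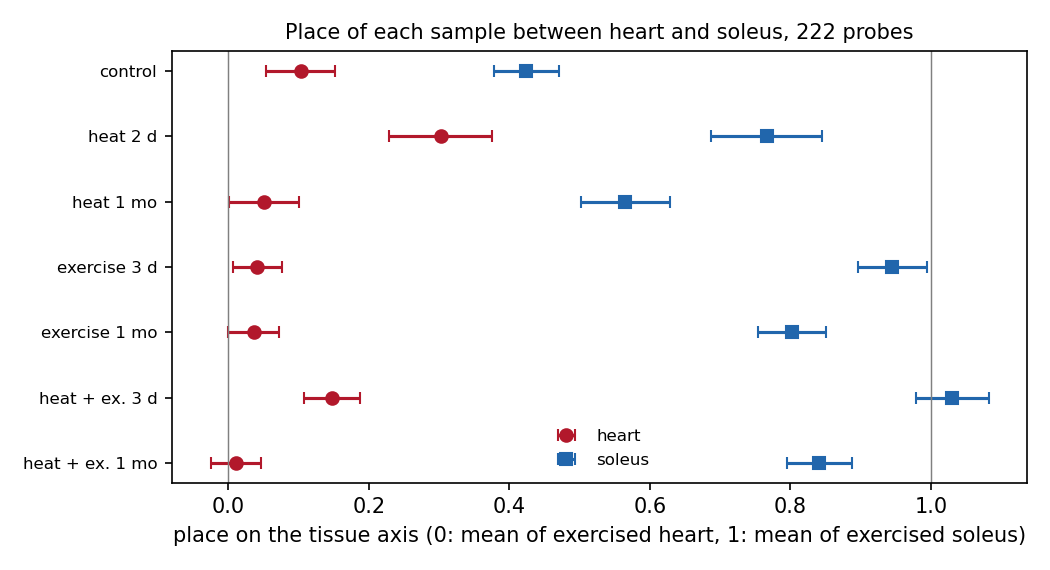
Place of each of the 14 samples on the axis from exercised heart (0) to exercised soleus (1), without units (horizontal axis), by condition (vertical axis), with heart as red circles and soleus as blue squares. Bars are bootstrap standard errors over 222 probes, and the soleus control at 0.424 and the soleus long heat sample at 0.565 lie below the exercised soleus samples, which lie between 0.802 and 1.03.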

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

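The test of heart signal in the soleus control and long heat samples came after the values had been seen, and R252 was singled out by its own values.

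R252 is given because its exercise effects in the tissues lay apart, at -0.38 in heart and -1.08 in soleus on the log2 scale, a difference of -0.699 (SE 0.21). The difference had a limma adjusted p (Benjamini-Hochberg) of 0.0303 over the 4 named probes and of 0.39 over all 531 probes, and none of the 38 exercise probes passed for the tissue difference when adjusted over that list. A tissue difference of R252 is therefore not established. In soleus R252 lay under the detection limit in 2 exercised samples. Its normalized intensity in soleus was 1359 after short and 1751 after long exercise, and 1207 after short and 1200 after long combined treatment. All 4 of these values lay under the common floor and were raised to it in the fit. The soleus effect of -1.08 and the tissue difference of -0.699 therefore depend on the floor and are bounds only.

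The heart and soleus samples of the control and of long heat were unusually alike. Their soleus minus heart difference was set against the tissue differences of the other 5 conditions. The slope was 0.338 ± 0.0315 in the controls and 0.539 ± 0.0692 after long heat. These slopes argue against samples that did not differ in tissue (slope under 0.25). On an axis of short and long heat alone, though, the controls had 0.273 ± 0.047, above 0 but not clear of that limit. The slopes of 0.338 and 0.539 also argue against an additive shift common to both tissues, which would keep the tissue difference (slope of at least 0.75). A hybridisation batch that alters the tissue difference itself is not addressed by that limit and stays open. Sharing of signal in both directions was to be argued against where a sample lay inside the range of the exercised samples of its tissue. After long heat, with the tissues 0.514 apart, the heart sample, at 0.051 ± 0.05, lay inside that range by more than 1 but under 2 standard errors. The upper edge, 0.148, comes from the heart short combined sample alone, and the other exercised heart samples lay at 0.011, 0.036 and 0.041, below 0.051. Such sharing therefore stays open after long heat. In the controls, 0.321 apart, it cannot be told apart from a real difference, since the heart control lies within 1 standard error of that edge. Heart signal in the soleus samples alone stays open too, with the soleus control at 0.424. A tissue difference that is larger in exercised samples stays open too. Its excess of 0.366 ± 0.081 on axes of the unexercised conditions rests on the alike samples themselves. These axes also differed. Each unexercised condition was set against the other unexercised ones, and each exercised condition against every pair of them. The slope of short heat, 0.666 ± 0.152, and the exercised mean, 0.822 ± 0.11, are therefore not on one axis and cannot be compared. On the differences of the other conditions short heat had a slope of 0.464 ± 0.0799, below long heat and below all 4 exercised conditions (0.82 to 0.923). Short heat alone does not decide the question.

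The ratio of the 2 deposited intensities of a probe was not constant within a sample. From the 1st to the 99th percentile of probes it varied 1.05-fold in the heart control and 1.02-fold in the soleus control, but 1.13-fold to 2.2-fold in the treated samples. A rescaling that depends on intensity would explain most of this spread, yet a smooth curve on intensity explained a median share of 0.04 of its variance over the treated samples (range 0.022 to 0.121), and one on the series table's intensity a median of 0.112 (up to 0.168). That low share is consistent with separate scaling of the pools before they were averaged, a hypothesis that the sources used here cannot settle. No biological explanation was tested for this pattern.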

How the results depend on the processing

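The analyses without a pseudocount, without the control and long heat samples, with tissue and exercise terms only, and with the condition as a random block were added after seeing the data; other alternatives were planned. Heat gave 0 calls in all 30 alternatives, and both tissue differences gave 0 in all 21. Soleus against heart stayed between 40 and 62 calls (45 to 85 with 1 sample left out, main count 60). The 38 exercise calls became 61 without normalization, 58 with the series table, 11 with probes above the floor in all samples, 1 without the controls, 0 in heart only, 0 in soleus only, 61 in the long arms, 0 in the short arms, 1 with a heat by exercise term, 0 without control and long heat samples, and 1 to 84 with 1 sample left out. With the condition as a random block they came to 40, at an estimated correlation of -0.02 between the tissues of a condition. The subsets hold fewer samples and the strict filter fewer probes by construction. With a heat by exercise term the exercise effect is the one in unheated samples alone. Otherwise the cause was not tested. Duration went from 0 to between 0 and 1 with 1 sample left out, and the departure from additivity from 0 to 3 without a filter. RG148 passed in 24 of 24 alternatives and RG153, R638 and RG032 in 23 of 23, not being tested above the floor in all samples (limma adjusted p up to 0.00287). R163 missed in 6 of 30, RG099 and R252 in 7 of 30 and RG011 in 15 of 31, with no change of sign.

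Counts of 2-fold differences from the control moved as follows. A larger pseudocount shrinks ratios and a stricter filter compares fewer probes by construction, and otherwise the cause was not tested. Without a pseudocount, the heart total was 125 and its counts were 38 (short heat), 23 (short exercise), 13 (short combined), 12 (long heat), 21 (long exercise) and 18 (long combined), and in soleus 345, with 84, 59, 53, 22, 65 and 62 in that order. With the pseudocount at 250, the heart total was 103, with 20 (short exercise), 10 (short combined), 10 (long heat), 17 (long exercise) and 15 (long combined), and in soleus 298, with 78, 49, 49, 15, 58 and 49. With it at 1774, heart gave 28 in all, 0 (long heat), 2 (long exercise) and 3 (long combined), and soleus 94, with 13 (short exercise), 2 (long heat), 14 (long exercise) and 10 (long combined). With both samples at or above the median, heart gave 15, with 9, 3, 0, 0, 1 and 2, and soleus 23, with 4, 2, 6, 1, 7 and 3. Under median scaling heart gave 71, with 14 (short exercise) and 9 (long heat), and soleus long heat 11. Without normalization heart gave 86, with 20 (short exercise), 12 (short combined), 11 (long heat) and 10 (long exercise), and soleus 83 (short heat) and 31 (short exercise). With the series table heart gave 89, with 21 (short exercise), 4 (short combined), 9 (long heat), 10 (long exercise) and 13 (long combined), and soleus 39 (short combined), 8 (long heat) and 45 (long exercise). The other 42 counts stayed within 1.5 times.

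No paired analysis was possible because each group holds 1 sample, so that replicate numbers pair nothing. The tissues were instead paired by condition, and without that block 59 probes passed. Alternatives for gene lists were not run, since the probes carry no gene names here. The detection limit leaves probes under 1200 with a bound only.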

Other observations

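The recurrence of effects, the matching of conditions across tissues and the counts of measured probes were examined after the values had been seen, as were the splits of whole conditions, while the relabelled sets of samples were planned.

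Effects estimated from different samples were correlated across probes. Over 222 probes, the correlation across probes of 2 exercise effects that share no sample had a median of 0.33 within a tissue (range -0.26 to 0.58, above 0 in 8 of 10) and 0.32 across tissues (range -0.17 to 0.5, above 0 in 12 of 16). For heat the medians were 0.03 within a tissue (range -0.31 to 0.21, above 0 in 6 of 10) and 0.08 across tissues (range -0.14 to 0.5, above 0 in 9 of 16). All but 1 of the 26 exercise pairs use a control or long heat sample, and the remaining pair had a correlation of 0.16. The 6 heat pairs without those samples had a median of 0.14 (range -0.14 to 0.21), so no recurrence beyond that of heat is shown without them. Probes are not independent replicates, and these pairs of estimates overlap in part, so no p is given.

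The likeness of the heart and soleus controls and long heat samples, already seen, also shows in a matching of conditions across tissues. The mean rank correlation was 0.83 for the same condition and 0.802 for others, and 11 of the 5040 ways to match the conditions gave as high a value (exact permutation, one-sided, p = 0.0022). Among the 5 conditions other than control and long heat the means were 0.788 and 0.782 (exact permutation over 120 matchings, one-sided, p = 0.092), so a general likeness of same-condition samples is not shown. The heart short heat sample had its lowest correlation with soleus, 0.737, for the soleus short heat sample. Every other heart sample also had its lowest correlation with soleus there (0.707 to 0.738), so this is not particular to short heat in heart.

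Sets of samples with permuted condition labels within each tissue showed how often such counts arise without the real labels. For exercise, 1 of the 100 sets, the real one, gave 38 or more probes, and the highest of the others gave 1. These sets treat the tissues as independent. With whole conditions as the unit and tissue and exercise as the only terms, 47 probes passed with the real labels. Of the 35 ways to take 4 of the 7 conditions as exercised, only the real one gave as many, and the highest other gave 19. A chance split is thus unlikely in both tests, though so few ways cannot give a very small share. Neither test can tell an exercise effect from the unusual control and long heat samples, without which the main model made 0 calls. For soleus against heart, 1 of the 64 ways to exchange the tissues within conditions, the real one, gave 60 or more probes. The highest other, 15, came from exchanging the short heat samples, so a chance split is unlikely there too. For heat, duration, the departure from additivity and both tissue differences the real count was 0. All 100 of 100 sets then give as many by construction, which says nothing about chance. The highest other counts were 38 for heat, 12 for duration, 2 for the departure from additivity, 11 for the tissue difference of heat and 8 for that of exercise. The set with 38 heat calls repeats the exercise comparison under another name, since the 8 samples it relabelled as heated were the 8 exercised ones. The highest of the remaining sets gave 1.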
